A study of Mus musculus with 4 samples.

How the data were processed

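The T cell receptor beta chain (TRB) was sequenced in CD4+ T cells of C57BL/6 mice carrying a Nur77-GFP reporter, in which green fluorescent protein is made when the receptor signals. Per the labels, the mice were 8 weeks old when the transverse aorta was constricted (25G), an operation that puts the left ventricle under pressure overload, and tissues were taken 8 weeks later. Cells of 3 mice were pooled. Per the labels' protocols, lymphoid tissue was dissociated mechanically and the left ventricle was digested with collagenase II, and 5000 sorted cells per site entered RNA isolation. The sort from thymus, inguinal lymph node and mediastinal lymph node was on CD3 and CD4, while the sort from left ventricle was also on GFP, so site and gate differ together. The labels do not name CD8, and whether immature CD4+CD8+ cells were left out of the thymic sort is not given in the sources used here. A SMARTer kit from Takara Bio for mouse alpha and beta chains was used for the libraries, per the labels' protocols, and no molecular identifiers are recorded in the files.

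Each library came as 1 table with 1 clonotype per line. The deposited clone counts are whole numbers of reads per clonotype, not normalized. The deposited clone fraction is each count divided by 1 constant per table, which exceeds the sum of the counts listed: the listed reads were 99.7% of it in thymus, 99.4% in inguinal node, 99.4% in mediastinal node and 99.4% in left ventricle. Per the file headers, a quality score gives the lowest base quality in the CDR3, and it was not used here. The deposited V, D and J hits carry an alignment score, and the hit listed at the front was taken. Clone numbers had gaps, with 1263 missing in thymus, 1569 in inguinal node, 474 in mediastinal node and 57 in left ventricle, so the tables do not hold every numbered clone. Reads were trimmed with Trimmomatic, per the submitters' processing notes. The aligner, the clone caller, their versions and the germline reference were not given in the sources used here. The thymus table held 3 blank lines, which were skipped, and 1 inguinal line had an unreadable TRBJ cell and was kept with TRBJ unassigned. Alpha chains were not analysed here.

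A clonotype was defined as 1 combination of CDR3 nucleotide sequence, best TRBV and best TRBJ, with alleles ignored. It was called productive when the CDR3 held no stop and no frameshift. The deposited tables held 2606608 reads in 4412 clonotypes for thymus, 1484612 reads in 2716 for inguinal node, 1210016 reads in 990 for mediastinal node and 966262 reads in 355 for left ventricle. This comes to 521, 297, 242 and 193 reads per sorted cell, in that order. Every productive clonotype entered the main values, whatever its count. Because each site had 1 library, no replicate check was possible and no p-value is given. The odds ratios and random draws compare single libraries and carry no replicate variation. Differences between sites are differences between these 4 libraries.

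Shares of clonotypes carry exact (Clopper-Pearson) 95% intervals and shares of reads carry Wilson 95% intervals. Both, and the limits given for a count of 0 (3 counts of the total), cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Clonality was 1 minus the Shannon entropy of read shares divided by its maximum. The inverse Simpson index gave the effective number of clonotypes. Overlap was measured as the number of shared clonotypes, as that number per 1000000 possible pairs, and as the Morisita-Horn index, which weights by reads and runs from 0 to 1. The distance between TRBV or TRBJ usage was the total variation distance in percent. The spread of indices and distances came from 200 resamples of clonotypes. Each distance was also set against 1000 random draws of both libraries from their pooled usage, a comparison chosen after the values were seen. A segment was called higher or lower only where the exact intervals of both shares did not overlap. Segment positions came from the GENCODE M21 annotation of GRCm38; the build used by the authors was not given in the sources used here. All 43 segments seen in the tables were found in that annotation.

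The definitions, comparisons, segment lists and naming rule were fixed before the data were examined. The clonotypes named by rule were the 10 with most reads in left ventricle, the 3 with most reads in each other site, and the 5 with most left ventricle reads among those found elsewhere. The segments named by rule were those of both lists, the 8 TRBV with the largest difference between left ventricle and thymus, the 4 with the largest difference between the nodes, and the 3 TRBJ with the largest difference between left ventricle and thymus. The lists were TRBV of invariant natural killer T (iNKT) cells (TRBV13-1, TRBV13-2, TRBV13-3, TRBV29 and TRBV1) and superantigen-linked TRBV (TRBV12-1, TRBV12-2, TRBV15 and TRBV16). Other clonotypes and segments named in the text, among them TRBV2, TRBV14, TRBV17, TRBJ2-1 and TRBJ2-7, were chosen after their values were seen.

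The alternatives were a minimum of 2 or 10 reads per clonotype, merging of clonotypes 1 substitution from another with at least 20 times the reads, equal reads in each library (941154, 100 draws), other clonotype definitions, the most abundant 319 clonotypes of each library, and weighting by reads. Removal of a clonotype where another library held at least 100 times its reads, and a requirement that the CDR3 start with C and end with F or W, were added after the data were seen. The functions were tested on simulated data. In 40 simulated pairs built from the clonotype sizes of left ventricle (319) and inguinal node (2353), with 20 planted shared clonotypes and reads carried over at a rate of 0.0001, the count of shared clonotypes was 192 on average without a read minimum, 20.0 with a minimum of 10 reads and 21.9 after the removal. A minimum of 10 reads drops every clonotype with fewer reads, whether truly shared or carried over. These counts therefore do not show how true sharing at few reads would be treated. The exact intervals covered the planted segment shares in 96.9% of cases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.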

Results

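The beta chain repertoire of CD4+ T cells was compared between 4 sites of mice with pressure overload of the heart: the thymus, where T cells mature, the inguinal lymph node, which does not drain the heart, the mediastinal lymph node, which does, and the left ventricle. The series set out to profile the receptor diversity of these cells site by site during cardiac dysfunction. Each site was 1 library of 5000 sorted cells from 3 pooled mice, and only the left ventricle cells were gated on the Nur77-GFP reporter of receptor signalling. The labels of the thymic sort name no CD8 gate, so thymus values are those of CD3+CD4+ cells whose maturity is not known. Productive reads numbered 2385457 in thymus, 1418004 in inguinal node, 1155773 in mediastinal node and 941154 in left ventricle.

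The left ventricle held the fewest clonotypes of the 4 libraries, and its 10 largest took the largest share of reads. It had 319 productive clonotypes, against 3604 in thymus, 2353 in inguinal node and 881 in mediastinal node, or 6.38, 72.1, 47.1 and 17.6 clonotypes per 100 sorted cells. The 10 largest clonotypes took 28.4% of left ventricle reads (Wilson 95% interval 28.3% to 28.5%), 14.5% in mediastinal node (14.5% to 14.6%), 3.64% in inguinal node (3.61% to 3.67%) and 2.92% in thymus (2.90% to 2.95%). The 100 largest took 99.2%, 54.1%, 22.3% and 17.5% in the same order. The effective number of clonotypes (inverse Simpson index) was 61.5 in left ventricle, 160 in mediastinal node, 866 in inguinal node and 1268 in thymus.

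The mediastinal node lay between the left ventricle and the other lymphoid sites by the share of its 10 largest clonotypes. The largest clonotype took 5.04% of reads in mediastinal node, 4.06% in left ventricle, 0.453% in inguinal node and 0.396% in thymus. Resampling clonotypes gave the share of the 10 largest an SD of 3.68 percentage points in mediastinal node and 2.68 in left ventricle. Clonality, which is 0 for equal clonotype sizes, was 0.246 in left ventricle, 0.150 in mediastinal node, 0.0905 in inguinal node and 0.0859 in thymus. Much of the left ventricle clonality came with clonotypes of very few reads: 173 of its 319 clonotypes (54.2%) had 1 read, and with a minimum of 10 reads it kept 120 clonotypes and had a clonality of 0.0925, below the 0.113 of mediastinal node. The same minimum left 3021 clonotypes in thymus, 1930 in inguinal node and 663 in mediastinal node. Relative to these numbers the left ventricle was not more concentrated, as 50% of reads lay in 20% of its clonotypes, against 16.02% in thymus, 16.7% in inguinal node and 12.97% in mediastinal node. With every clonotype counted it was the most concentrated by this measure, at 7.52% against 13.5% in thymus, 13.7% in inguinal node and 9.88% in mediastinal node.

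**Figure D1:**
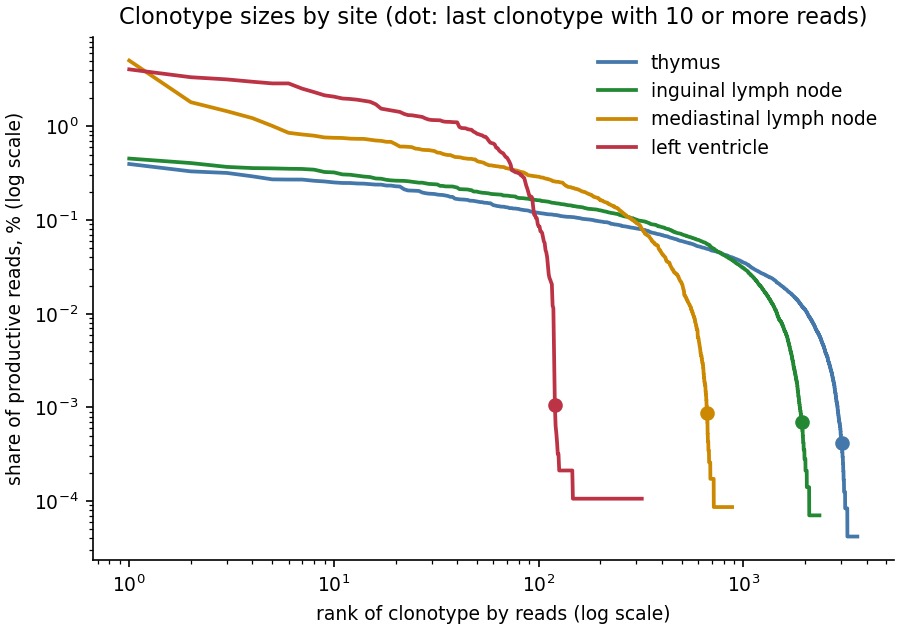
Share of productive reads (percent, log scale) of each clonotype against its rank by reads (log scale), with 1 line per site; the dot marks the last clonotype with 10 or more reads. The left ventricle line lies highest over most of its largest clonotypes and drops after 120 clonotypes, while the lines of mediastinal node, inguinal node and thymus reach 663, 1930 and 3021.

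The 10 largest left ventricle clonotypes used 8 TRBV segments, and TRBV20 and TRBV13-3 each occurred in 2 of them. The largest was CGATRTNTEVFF (TRBV20 with TRBJ1-1) with 38192 reads, followed by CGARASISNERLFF (TRBV20 with TRBJ1-4) with 31477 reads and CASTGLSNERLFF (TRBV19 with TRBJ1-4) with 29839 reads. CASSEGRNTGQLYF (TRBV13-3) had 28170 reads, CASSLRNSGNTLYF (TRBV3) 27044, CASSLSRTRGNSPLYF (TRBV29) 27042 and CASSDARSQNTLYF (TRBV13-1) 23764. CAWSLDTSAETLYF (TRBV31) had 21836 reads, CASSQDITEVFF (TRBV5) 20178 and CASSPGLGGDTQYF (TRBV13-3) 19531. None of these 10 exceeded 10 reads in another library. All were rearranged in the TRB locus on chromosome 6 (GRCm38), where TRBV20 lies at 41188273 to 41188977, TRBJ1-1 at 41533864 to 41533911 and TRBJ1-4 at 41534811 to 41534861.

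The largest clonotypes of the lymphoid sites were other receptors. In mediastinal node they were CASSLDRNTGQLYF (TRBV3 with TRBJ2-2) with 58237 reads, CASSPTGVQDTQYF (TRBV19 with TRBJ2-5) with 20934 reads and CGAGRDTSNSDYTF (TRBV20 with TRBJ1-2) with 16775 reads. In inguinal node they were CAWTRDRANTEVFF (TRBV31) with 6427 reads, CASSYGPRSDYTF (TRBV4) with 5754 and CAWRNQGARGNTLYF (TRBV31) with 5235. In thymus they were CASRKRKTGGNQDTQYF (TRBV4) with 9458 reads, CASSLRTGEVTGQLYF (TRBV29) with 7893 and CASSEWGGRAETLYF (TRBV13-1) with 7594.

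Whether heart T cell clonotypes were also present in the draining node, the non-draining node or the thymus was asked by matching clonotypes between libraries. With every deposited clonotype counted, 146 of the 319 left ventricle clonotypes were found in thymus (45.8%, exact 95% interval 40.2% to 51.4%), 132 in inguinal node (41.4%, 35.9% to 47.0%) and 112 in mediastinal node (35.1%, 29.9% to 40.6%). Those clonotypes held 71.5%, 73.4% and 57.6% of left ventricle reads, but their median count in the other library was 3 reads in each case. The 5 with most left ventricle reads were the 5 largest clonotypes of that library, and their highest count elsewhere was the 10 reads of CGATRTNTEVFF in thymus and in inguinal node. With a minimum of 10 reads in both libraries, 2 of 120 left ventricle clonotypes were found in thymus (1.67%, 0.202% to 5.89%), 3 in inguinal node (2.50%, 0.519% to 7.13%) and 2 in mediastinal node (1.67%, 0.202% to 5.89%). Of the 199 left ventricle clonotypes under 10 reads, 171 were present in another library.

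The clonotype most abundant in both the left ventricle and its draining node was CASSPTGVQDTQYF, the second largest of the mediastinal node, with 20934 reads there and 7546 reads (0.802%) in left ventricle. It had 1 read in inguinal node and none in thymus, and its CDR3 read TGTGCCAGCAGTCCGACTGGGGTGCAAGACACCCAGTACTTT. With clonotypes defined by nucleotide sequence and segments, it gave the mediastinal node and left ventricle the highest Morisita-Horn overlap of the 6 pairs, 0.0130 with a resampling SD of 0.0129. Defined by CDR3 amino acids, the highest was between the nodes (0.0201 against 0.0136). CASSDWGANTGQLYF (TRBV13-1 with TRBJ2-2) had 4657 reads in left ventricle and 1494 in inguinal node. The other pairs had Morisita-Horn values of 0.00171 (inguinal and mediastinal node), 0.000813 (inguinal node and left ventricle), 0.000588 (thymus and inguinal node), 0.000139 (thymus and left ventricle) and 0.000128 (thymus and mediastinal node). Thymus and left ventricle fell to 2.77e-05 with at least 10 reads per clonotype and to 7.70e-06 after removal of clonotypes with 100 times the reads in another library.

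Sharing was rare between all libraries once short sequences and large read imbalances were set aside. With 10 or more reads in both libraries, conserved CDR3 ends, and no library holding 100 times the reads of the other, 6 clonotypes were shared by the nodes, 2 by thymus and inguinal node, 1 by inguinal node and left ventricle and 1 by mediastinal node and left ventricle. Thymus and mediastinal node shared 0. Thymus shared 0 of the 118 left ventricle clonotypes left under these conditions, which allows a share of up to 2.54%. The 6 clonotypes of the nodes were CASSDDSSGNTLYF (6503 reads in mediastinal and 651 in inguinal node), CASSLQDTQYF (1865 and 601), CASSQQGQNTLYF (1687 and 1190), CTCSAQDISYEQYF (799 and 1174), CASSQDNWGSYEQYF (502 and 1032) and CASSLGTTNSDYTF (319 and 1151). Per 1000000 possible pairs these counts came to 12.8 for mediastinal node and left ventricle, 4.41 for inguinal node and left ventricle and 4.73 for the nodes, and those with the left ventricle rest on 1 clonotype each. The conditions set aside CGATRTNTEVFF, with its 10 reads in thymus and in inguinal node, and short sequences without the conserved cysteine such as YAEQFF with TRBV21, which had 1362 reads in thymus, 926 in inguinal node, 487 in mediastinal node and 108 in left ventricle.

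**Figure D2:**
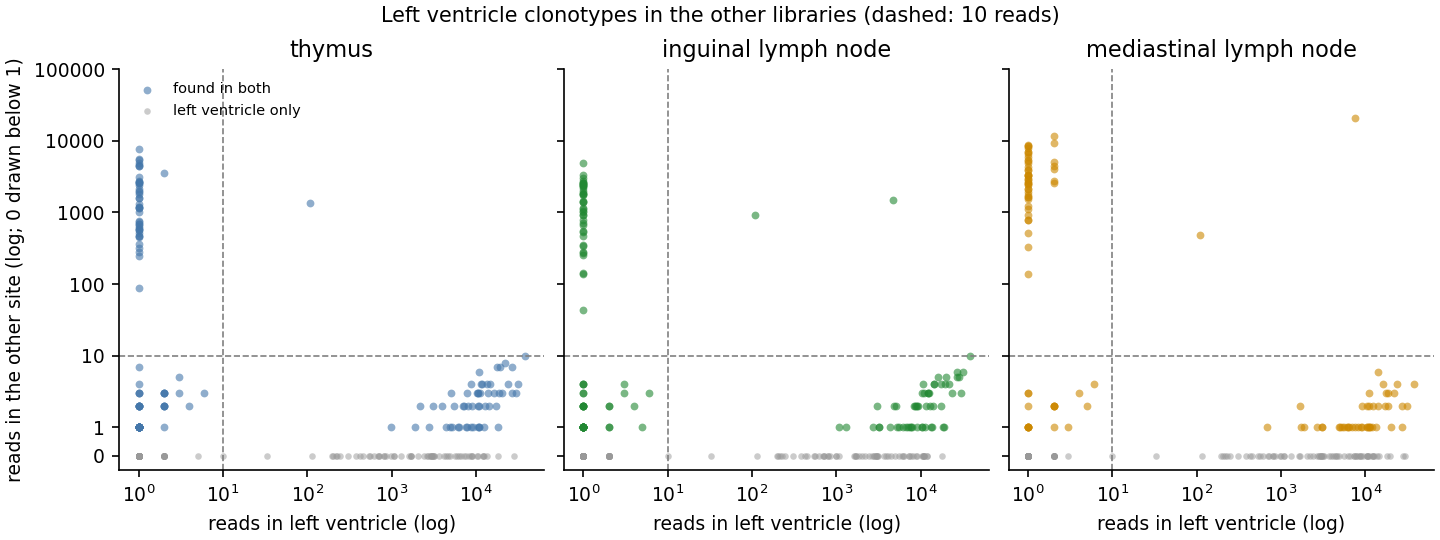
Reads of each left ventricle clonotype in the left ventricle (horizontal, log scale) and in thymus, inguinal node or mediastinal node (vertical, log scale, with 0 drawn below 1); coloured points are clonotypes found in both libraries, grey points those found in the left ventricle only, and dashed lines mark 10 reads. Points with 10 or more reads in both libraries number 2 in thymus, 3 in inguinal node and 2 in mediastinal node.

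Several TRBV segments differed in use between thymus and the other sites. TRBV31, the segment that lies downstream of the constant regions in opposite orientation (chromosome 6, 41557691 to 41558452), was used by 5.08% of thymus clonotypes (exact 95% interval 4.38% to 5.85%) and was higher in left ventricle (12.5%, 9.11% to 16.7%), inguinal node (9.82%, 8.64% to 11.1%) and mediastinal node (9.31%, 7.47% to 11.4%). TRBV20 was higher in left ventricle (7.84%, 5.14% to 11.4%) than in thymus (4.30%, 3.66% to 5.02%), and it took 16.01% of left ventricle reads against 5.45% in thymus. TRBV13-3 was higher in left ventricle (10.97%) and inguinal node (8.33%) than in thymus (5.72%). With a minimum of 10 reads the intervals of left ventricle and thymus still did not overlap for TRBV31 (11.7% against 4.37%) and TRBV20 (10% against 3.94%), while they overlapped for TRBV13-3 (9.17% against 5.30%). Removal of clonotypes with 100 times the reads in another library made the TRBV20 intervals overlap (7.45% against 3.96%).

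TRBV12-1 (41113550 to 41114067) and TRBV12-2 (41118851 to 41119364), which encode the Vβ5 family, were lower outside the thymus. TRBV12-1 was used by 6.88% of thymus clonotypes (6.08% to 7.76%), 1.10% in inguinal node (0.723% to 1.61%) and 2.61% in mediastinal node (1.66% to 3.89%). In left ventricle it was 3.45% (1.73% to 6.09%), which overlapped the thymus and was higher than inguinal node. Those 11 left ventricle clonotypes held 13 reads in all, each was present in another library, and with a minimum of 10 reads TRBV12-1 was found in 0 of 120 left ventricle clonotypes, which allows up to 2.50%, against 7.55% in thymus and 0.933% in inguinal node. TRBV12-2 was used by 3.39% of thymus clonotypes (2.82% to 4.03%) and was lower in inguinal node (1.02%), mediastinal node (0.681%) and left ventricle (0.627%, 0.0760% to 2.25%). Its left ventricle and thymus intervals overlapped with a minimum of 10 reads (0.833% against 3.38%). TRBV3 was at 4.08% in left ventricle and 6.38% in thymus, with overlapping intervals.

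Both nodes differed from thymus in the same segments for the most part. TRBV12-1, TRBV12-2, TRBV17 and TRBV29 were lower and TRBV31 was higher in each node than in thymus, and this held with a minimum of 10 reads. TRBV17 was at 3.39% in thymus, 1.19% in inguinal node and 1.02% in mediastinal node, and TRBV29 at 3.47%, 1.44% and 1.48%. TRBV1, TRBV2 and TRBV13-3 were also higher in inguinal node than in thymus, and TRBV5 was higher and TRBV14 lower in mediastinal node than in thymus. TRBV13-3 was higher in mediastinal node too with a minimum of 10 reads (8.75% against 5.30% in thymus). The distance between TRBV profiles was 15.8% for thymus and inguinal node (resampling SD 1.02), 17.6% for thymus and mediastinal node (1.31) and 7.92% for both nodes (1.54). The left ventricle lay at 19.9% from thymus (2.42), 15.6% from inguinal node (2.29) and 13.9% from mediastinal node (2.78). Random draws from the pooled usage of each pair, at the sizes of its libraries, gave a 95th percentile of 5.87% for thymus and inguinal node, 8.43% for thymus and mediastinal node and 13.2% for thymus and left ventricle, all below the observed distance, while the distance between the nodes (95th percentile 8.86%) and that of mediastinal node and left ventricle (14.2%) did not exceed theirs. For inguinal node and left ventricle the percentile was 13.3%. The draws treated the libraries as sharing no clonotypes, but 112 of the 319 left ventricle clonotypes were also found in mediastinal node. The nodes shared 171. Shared clonotypes lower an observed distance, so a distance within the draws does not show that both libraries were alike. No draws were made with a read minimum. Weighted by reads, the distances of the left ventricle were 29.0% from thymus, 25.9% from inguinal node and 25.7% from mediastinal node, against 24.5% for thymus and mediastinal node, 18.3% for thymus and inguinal node and 14.3% for both nodes. No random draws were made for the distances weighted by reads.

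The draining and the non-draining node were close in segment usage. TRBV5 was higher in mediastinal node (11.2%, 9.23% to 13.5%) than in inguinal node (7.86%, 6.81% to 9.02%), but the intervals overlapped with a minimum of 10 reads (11.2% against 8.50%). TRBV12-1 was higher in mediastinal node, and its intervals also overlapped with that minimum (1.81% against 0.933%). TRBV13-2 (8.17% in mediastinal and 10.3% in inguinal node) and TRBV20 (6.47% and 4.97%) had overlapping intervals. No TRBV differed between left ventricle and mediastinal node by this criterion. TRBV1 was lower in left ventricle (2.51%, 1.09% to 4.88%) than in inguinal node (6.76%, 5.78% to 7.85%). The intervals of this order overlapped with a minimum of 10 reads (2.50% against 7.20%). In mediastinal node TRBV1 was at 5.45% (4.04% to 7.16%), also above left ventricle, but its 881 clonotypes gave a wider interval than the 2353 of inguinal node.

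**Figure D3:**
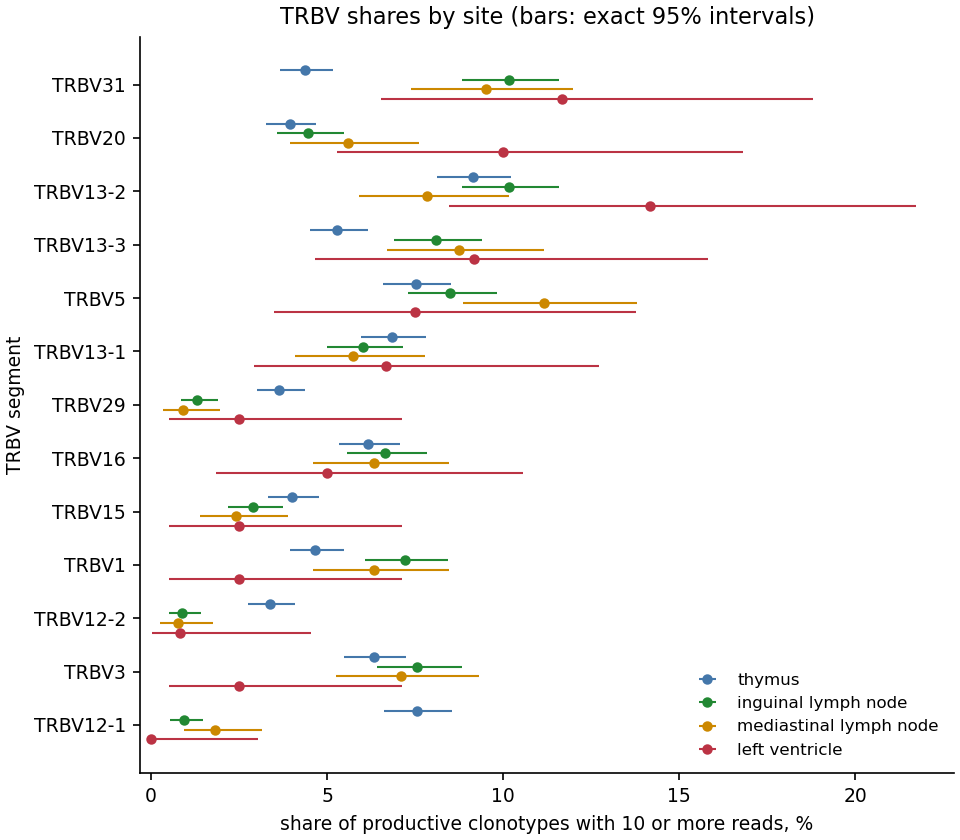
Share of productive clonotypes with 10 or more reads (percent, horizontal) that use each TRBV segment named by rule (vertical), with points for the 4 sites and bars for exact 95% intervals. TRBV12-1 stands at 7.55% in thymus and 0 of 120 clonotypes in left ventricle, and TRBV31 at 4.37% in thymus and 11.7% in left ventricle.

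No TRBJ was called higher or lower in left ventricle than in thymus: TRBJ2-4 was at 6.90% and 8.91%, TRBJ1-1 at 12.2% and 10.3%, and TRBJ2-5 at 15.0% and 13.2%. TRBJ2-7 was higher in inguinal node (18.2%, 16.7% to 19.9%) than in thymus (15.2%, 14.02% to 16.4%). TRBJ2-1 was lower in inguinal node (8.19%) than in thymus (11.2%) with a minimum of 10 reads. The TRBJ distance ranged from 3.62% for thymus and mediastinal node to 8.11% for inguinal node and left ventricle. Only thymus and inguinal node (5.08%) exceeded the 95th percentile of random draws from their pooled usage (4.76%). These draws too ignored clonotypes shared by both libraries, so they do not show that the other pairs were alike. The distance of thymus and left ventricle rose from 6.80% to 11.5% after removal of clonotypes with 100 times the reads in another library, that of mediastinal node and left ventricle rose from 5.06% to 9.45% with at least 10 reads per clonotype, and weighted by reads the 6 distances ran from 9.79% to 15.3%. Such distances grow as fewer clonotypes are compared. At full library sizes the random draws already averaged 7.55% for thymus and left ventricle and 8.41% for mediastinal node and left ventricle. No draws were made at the reduced sizes or with weighting, so these rises are not read as changes in TRBJ usage.

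Segments used by iNKT cells, which conventional T cells use too, had shares with overlapping intervals: 29.9% of clonotypes in thymus (28.4% to 31.4%), 32.6% in inguinal node (30.7% to 34.6%), 29.1% in mediastinal node (26.1% to 32.2%) and 29.5% in left ventricle (24.5% to 34.8%). With a minimum of 10 reads the left ventricle share was 35.0% (26.5% to 44.2%), which still overlapped the other sites. Weighted by reads it was 34.7%, against 29.2% in thymus, 30.1% in inguinal node and 25.7% in mediastinal node. Of the 5 segments of this list, TRBV13-3 was higher in left ventricle than in thymus, and the other 4 had overlapping intervals, with TRBV1 at 2.51% against 4.61% and TRBV13-1 at 4.08% against 6.58%. The TRBV13 family and TRBV19, which mucosal-associated invariant T cells favour, made up 24.8% and 5.64% of left ventricle clonotypes and 21.8% and 6.10% of thymus clonotypes.

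The superantigen-linked segments, whose cells are deleted in strains with the class II molecule I-E that C57BL/6 lacks, were higher in thymus (19.98%, 18.7% to 21.3%) than in inguinal node (11.5%, 10.2% to 12.8%), mediastinal node (11.5%, 9.44% to 13.8%) and left ventricle (12.9%, 9.38% to 17.0%). The left ventricle share was 8.33% (4.07% to 14.8%) with a minimum of 10 reads, or 10 of 120 clonotypes against 41 of 319. That minimum takes out all 11 of its TRBV12-1 clonotypes, and also others of the list: TRBV16 went from 16 clonotypes to 6, TRBV15 from 12 to 3 and TRBV12-2 from 2 to 1. Of the 4 members, TRBV12-1 and TRBV12-2 were lower in both nodes than in thymus. TRBV16 was at 5.94% in thymus and 5.02% in left ventricle and TRBV15 at 3.77% and 3.76%, with overlapping intervals in every site.

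CDR3 loops were longer in thymus than in the inguinal node. The mean length was 14.2 amino acids in thymus and 13.8 in inguinal node, a difference of 0.423 with an SE over clonotypes of 0.0444. In mediastinal node and left ventricle the mean was 14.1 and 14.2, but a few CDR3 of more than 25 residues, 3 and 2 of them and all under 10 reads, raised it. With a minimum of 10 reads the means were 14.3 in thymus, 13.8 in inguinal node, 13.8 in mediastinal node and 13.98 in left ventricle, and thymus exceeded mediastinal node by 0.451 (SE 0.0661) and left ventricle by 0.301 (SE 0.136). The distance between the V and J segments, which holds the added and D nucleotides, was 9.36 nucleotides in thymus and 8.45 in inguinal node with the same minimum, a difference of 0.909 (SE 0.137).

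**Figure D4:**
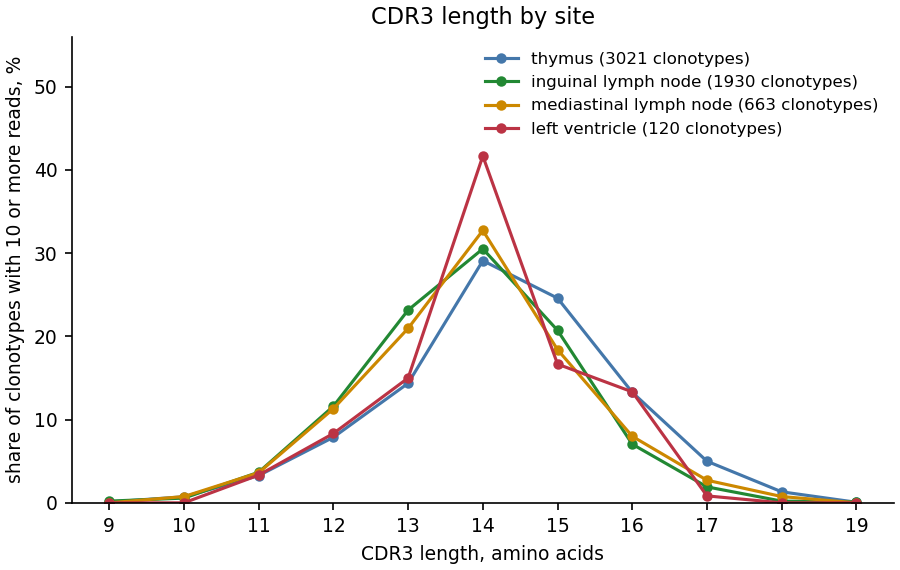
Share of productive clonotypes with 10 or more reads (percent, vertical) at each CDR3 length in amino acids (horizontal), with 1 line per site. The thymus line lies to the right of the inguinal and mediastinal node lines, with means of 14.3, 13.8 and 13.8 amino acids.

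Paired hydrophobic residues at CDR3 positions 6 and 7, counted from the conserved cysteine and described for self-reactive receptors, were rare in all 4 libraries. They occurred in 0.999% of clonotypes in thymus (0.701% to 1.38%), 1.06% in inguinal node (0.689% to 1.56%), 1.14% in mediastinal node (0.546% to 2.08%) and 1.57% in left ventricle (0.511% to 3.62%), and a difference was not detectable at this depth. There were 1.01 nucleotide sequences per CDR3 amino acid sequence in thymus, 1.02 in inguinal node, 1.01 in mediastinal node and 1.01 in left ventricle.

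Non-productive rearrangements were most frequent in thymus. They took 8.48% of thymus reads (8.45% to 8.52%), 4.49% in inguinal node (4.45% to 4.52%), 4.48% in mediastinal node (4.45% to 4.52%) and 2.60% in left ventricle (2.57% to 2.63%). Over clonotypes the thymus was at 18.3% (17.2% to 19.5%), above inguinal node at 13.4% (12.1% to 14.7%), mediastinal node at 11.01% (9.13% to 13.1%) and left ventricle at 10.1% (7.20% to 13.8%). With a minimum of 10 reads the left ventricle interval, 5.83% to 16.9%, overlapped that of thymus, 13.5% to 15.8%.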

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

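The limits to read beside every value are that each site had 1 library, and that 54.2% of the left ventricle clonotypes rested on 1 read, against 10.7% in thymus. Removal of clonotypes with far more reads elsewhere, and the requirement of conserved CDR3 ends, were chosen after the data were seen. A value was taken as moved when it left its 95% interval. That interval was binomial for shares of clonotypes. It came from 200 resamples of clonotypes for clonality, shares of reads, mean CDR3 length, Morisita-Horn overlap and distances. Clonotype counts, the inverse Simpson index, shared clonotypes per 1000000 pairs and nucleotide sequences per amino acid sequence were instead taken as moved beyond a change of 1.5 times. A minimum of 10 reads turned several orders, of which examples follow. Left ventricle minus mediastinal node was -0.0207 for clonality, against 0.0959 with every clonotype. Left ventricle minus inguinal node was -0.933 percentage points for the TRBV12-1 share, which was also -0.222 with a minimum of 2 reads. For the concentration of reads given in the Results, left ventricle went from the lowest share of clonotypes (7.52%) to the highest (20%). Mediastinal minus inguinal node for TRBV13-3 went from -0.157 to 0.665 percentage points, with overlapping intervals. The non-productive share of clonotypes was 10.1% in left ventricle against 11.01% in mediastinal node. It became 10.4% against 7.79%, with overlapping intervals in both settings. Thymus minus left ventricle in CDR3 length was 0.0124 (SE 0.260) with every clonotype and -0.196 (SE 0.429) after the removal. The inverse Simpson index, the share of reads in the 10 largest clonotypes and the nucleotide sequences per amino acid sequence stayed within those bounds in each alternative run for them. The same held for the values recomputed after merging of clonotypes 1 substitution from a far larger one, after requiring conserved ends, and with clonotypes defined by the CDR3 nucleotide sequence alone. The merging required at least 20 times the reads. In left ventricle, clonotypes 1 nucleotide from a larger one had up to 13.5% of its reads, so such clonotypes could stay unmerged. The merged values therefore do not show that altered copies had no effect. The nucleotide sequences per amino acid sequence lay near 1, so a change of 1.5 times could hardly occur. Among the other comparisons of named segments, a minimum of 10 reads ended 5 calls and added 2, a minimum of 2 reads ended 5 and added 2, and removal of clonotypes with far more reads elsewhere ended 3 and added 2. No paired analysis was possible because each site had 1 library. The minimum of 10 reads and the removal act by construction on clonotypes with few reads. For the other moved values, which follow by setting, the cause was not tested.

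With a minimum of 2 reads per clonotype, clonality was 0.0733 (thymus), 0.0769 (inguinal node) and 0.128 (left ventricle). The number of productive clonotypes was 146 (left ventricle). Superantigen-linked TRBV made up 8.90% (left ventricle). Left ventricle clonotypes found elsewhere made up 35.6% (thymus), 27.4% (inguinal node) and 23.3% (mediastinal node) of its clonotypes, and 57.8% (thymus), 54.8% (inguinal node) and 34.2% (mediastinal node) of its reads. The number of shared clonotypes per 1000000 pairs was 7.42 (thymus/inguinal), 18.2 (thymus/mediastinal) and 28.0 (inguinal/mediastinal). The TRBV distance was 27.1% (thymus/ventricle) and 19.8% (mediastinal/ventricle). With a minimum of 10 reads, clonality was 0.0662 (thymus), 0.0673 (inguinal node), 0.113 (mediastinal node) and 0.0925 (left ventricle). The number of productive clonotypes was 120 (left ventricle). iNKT-associated TRBV made up 35.0% (left ventricle). Superantigen-linked TRBV made up 8.33% (left ventricle). Left ventricle clonotypes found elsewhere made up 1.67% (thymus), 2.50% (inguinal node) and 1.67% (mediastinal node) of its clonotypes, and 4.07% (thymus), 4.57% (inguinal node) and 0.813% (mediastinal node) of its reads. The number of shared clonotypes per 1000000 pairs was 0.858 (thymus/inguinal), 0.999 (thymus/mediastinal), 5.52 (thymus/ventricle), 6.25 (inguinal/mediastinal), 13.0 (inguinal/ventricle) and 25.1 (mediastinal/ventricle). The TRBV distance was 18.1% (thymus/inguinal) and 26.4% (thymus/ventricle). The Morisita-Horn overlap was 2.77e-05 (thymus/ventricle). The TRBJ distance was 9.45% (mediastinal/ventricle). At equal reads (mean of 100 draws of 941154), clonality was 0.0771 (thymus) and 0.0857 (inguinal node). Left ventricle clonotypes found elsewhere made up 33.8% (thymus) of its clonotypes, and 52.2% (thymus) of its reads. The number of shared clonotypes per 1000000 pairs was 16.02 (thymus/inguinal) and 36.7 (thymus/mediastinal). Over the 319 most abundant clonotypes of each library, left ventricle clonotypes found elsewhere made up 5.64% (thymus), 6.58% (inguinal node) and 13.5% (mediastinal node) of its clonotypes, and 0.00202% (thymus), 0.497% (inguinal node) and 0.807% (mediastinal node) of its reads. The number of shared clonotypes per 1000000 pairs was 0 (thymus/inguinal), 0 (thymus/mediastinal) and 0 (inguinal/mediastinal). The Morisita-Horn overlap was 8.02e-06 (thymus/ventricle). With clonotypes defined by the CDR3 amino acid sequence, the Morisita-Horn overlap was 0.00778 (thymus/inguinal), 0.00664 (thymus/mediastinal), 0.000279 (thymus/ventricle) and 0.0201 (inguinal/mediastinal). Weighted by reads, the mean CDR3 length was 13.7 amino acids (inguinal node) and 13.8 amino acids (mediastinal node). iNKT-associated TRBV made up 30.1% (inguinal node) and 25.7% (mediastinal node). Superantigen-linked TRBV made up 10.2% (inguinal node) and 6.56% (left ventricle). The TRBV distance was 18.3% (thymus/inguinal), 24.5% (thymus/mediastinal), 29.0% (thymus/ventricle), 14.3% (inguinal/mediastinal), 25.9% (inguinal/ventricle) and 25.7% (mediastinal/ventricle). The TRBJ distance was 9.79% (thymus/inguinal), 9.93% (thymus/mediastinal), 13.5% (thymus/ventricle), 12.4% (inguinal/mediastinal), 13.6% (inguinal/ventricle) and 15.3% (mediastinal/ventricle). At positions 7 and 8, the share of clonotypes with paired hydrophobic residues was 1.42% (thymus). With alanine in place of tyrosine among the residues, the share of clonotypes with paired hydrophobic residues was 2.22% (thymus), 1.57% (inguinal node) and 2.16% (mediastinal node). Counted over clonotypes instead of reads, the non-productive share was 18.3% (thymus), 13.4% (inguinal node), 11.01% (mediastinal node) and 10.1% (left ventricle). After removal of clonotypes with at least 100 times as many reads in another library, clonality was 0.0797 (thymus), 0.0818 (inguinal node) and 0.170 (left ventricle). The number of productive clonotypes was 188 (left ventricle). Left ventricle clonotypes found elsewhere made up 17.6% (thymus), 12.8% (inguinal node) and 9.57% (mediastinal node) of its clonotypes, and 0.0170% (thymus), 0.511% (inguinal node) and 0.817% (mediastinal node) of its reads. The number of shared clonotypes per 1000000 pairs was 6.72 (thymus/inguinal), 11.3 (thymus/mediastinal), 51.5 (thymus/ventricle), 19.4 (inguinal/mediastinal), 58.5 (inguinal/ventricle) and 127 (mediastinal/ventricle). The Morisita-Horn overlap was 7.70e-06 (thymus/ventricle). The TRBJ distance was 11.5% (thymus/ventricle) and 9.605% (mediastinal/ventricle).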

Other observations

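The tests on clonotypes found at trace level, on the evenness of clonotype sizes, on the ratio of productive to non-productive odds and on the odds in mediastinal node, and the receptors and pairs described in the next 2 paragraphs, were chosen after the values were seen.

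The largest and the fourth largest clonotype of the mediastinal node shared a TRBV and the start of the CDR3. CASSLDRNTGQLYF (TRBV3 with TRBJ2-2) had 58237 reads (5.04%) and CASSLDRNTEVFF (TRBV3 with TRBJ1-1) had 14140 reads (1.22%). They carried different TRBJ and different nucleotides in the shared part, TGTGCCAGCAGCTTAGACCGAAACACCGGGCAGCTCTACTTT and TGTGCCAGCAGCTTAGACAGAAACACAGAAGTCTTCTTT, so they were separate rearrangements. Together they took 6.26% of mediastinal node reads and had at most 4 reads in inguinal node and 3 in thymus, and neither was found in the left ventricle library. Among the 10 largest clonotypes, this was the only pair with the same TRBV and the same 8 opening residues in mediastinal node, and thymus, inguinal node and left ventricle had 0. Among the 100 largest, mediastinal node had 2 such pairs, left ventricle 1, and thymus and inguinal node 0. Another TRBV3 clonotype, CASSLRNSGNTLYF, also opened with CASSL. The N that ends the 8 residues also occurred with TRBJ2-2 in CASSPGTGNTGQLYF and with TRBJ1-1 in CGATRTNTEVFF. The likeness not found in other clonotypes with these segments was therefore shorter than 8 residues. The length of 8 was set after this pair was seen, so these counts are no test.

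TRBD2 lies downstream of the TRBJ1 cluster, at 41542163 to 41542176 on chromosome 6 (GRCm38), yet it was the named D segment in 9.32% of thymus clonotypes with a TRBJ1 and a D (exact 95% interval 7.43% to 11.5%), 8.46% in inguinal node, 8.49% in mediastinal node and 7.79% in left ventricle. With a TRBJ2 the share was 54.7%, 51.9%, 54.1% and 51.0%. The D named was the front-listed hit to a short segment, as TRBD1 spans only 41533201 to 41533212. Wrong naming of the D was not tested, so these shares do not show joins of TRBD2 to TRBJ1. The shares with a TRBJ2 carry the same limit.

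The left ventricle clonotypes found elsewhere at trace level were set against reads carried over between libraries and against cells of the same clone in both sites. Among left ventricle clonotypes with 1000 or more reads, those above the median by reads were found in another library in 70.8% of 144 comparisons and the others in 36.1% of 144, where each of 48 clonotypes was compared with 3 libraries, a difference of 34.7 percentage points (23.2 to 46.2 over resampled clonotypes), consistent with carry-over in proportion to reads. Of those found, 0 of 54 in thymus, 1 of 55 in inguinal node and 1 of 45 in mediastinal node (2.22%, 0.0562% to 11.8%) reached the median reads of that library, which restates that they were at trace level. Without the clonotypes that had 1% or more of their reads elsewhere, which were 0 in thymus, 1 in inguinal node and 1 in mediastinal node, the rate was 16.2 reads per 100000 left ventricle reads in thymus, 14.4 in inguinal node and 8.24 in mediastinal node, and between 1.74 and 7.66 for the 9 other directions, the highest being mediastinal into inguinal node. Cells of the same clone in the other site cannot be told apart from carry-over by these counts, because larger clones would also be found more often and a few cells with little receptor RNA would give few reads, and the step at which reads may have crossed stays open too.

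The small number of left ventricle clonotypes was set against sequencing depth, against a smaller input of cells or transcripts, and against expansion of few clones. Depth is argued against: at equal reads the thymus held 24.0 times as many clonotypes with 10 or more reads (range over 100 draws 23.9 to 24.1). A smaller input stays possible. The coefficient of variation of clonotype sizes was 0.979 (resampling SD 0.0757) against 1.18 in thymus, 1.11 in inguinal node and 1.78 in mediastinal node. Clonality with a minimum of 10 reads gave another order, with left ventricle (0.0925) above thymus (0.0662) and inguinal node (0.0673) and below mediastinal node (0.113). Evenness therefore does not decide for a smaller input. Expansion of a small number of clones among the 5000 sorted cells cannot be told apart from a smaller input, since the left ventricle minus the highest other coefficient was -0.799 but clones expanded to equal sizes would be even too. Tissue and the GFP gate, which differ together here, stay open as untested biological explanations.

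The higher use of TRBV12-1 and TRBV12-2 in thymus was set against reads carried over, exchange of calls between both segments and unequal amplification. With clonotypes under 10 reads and those with far more reads elsewhere removed, the odds ratio of thymus against inguinal node was 6.64 (exact conditional 95% interval 4.65 to 9.74). With only those under 10 reads removed it was also 6.64. Beyond the minimum, the removal changed thymus only from 3021 to 3020 clonotypes and inguinal node from 1930 to 1929, so its value adds nothing to the other. Both values pool the segments. An exchange of calls between the segments is argued against, as is carry-over at trace level, which the minimum takes out. In non-productive clonotypes, which are amplified alike but not selected for their protein, the odds ratio was 1.78 (0.910 to 3.75), below the productive interval of 4.65 to 9.74. The productive odds ratio was 3.73 times as high, which argues against unequal amplification or alignment as the whole cause in this comparison and is consistent with different productive receptors, as a hypothesis. Against mediastinal node the odds ratio was 4.66 (2.84 to 8.16) in productive and 1.09 (0.410 to 3.66) in non-productive clonotypes, a ratio of 4.28, and since these intervals overlap and 5 non-productive mediastinal clonotypes used the segments, amplification and receptors cannot be told apart there, and selection or immature cells in the thymic sort were not tested.

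Convergent receptors among heart T cells were looked for as pairs of left ventricle clonotypes (10 or more reads) with the same TRBV and a CDR3 differing at no more than 1 residue. There were 4 such pairs, above the 95th percentile of 1000 equal draws of 120 clonotypes from thymus (1), inguinal node (2) and mediastinal node (2), so the bound set for convergence in advance was passed. That bound does not separate convergence from altered copies: the left ventricle library was used whole, while draws from larger libraries rarely keep both a clonotype and its copy. After the pairs were seen the result was also read as undecided, for the reason that follows. All 4 pairs differed at 1 nucleotide and shared the TRBJ, and the smaller member had 4.90% to 13.5% of the reads of the larger, as in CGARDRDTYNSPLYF (9041 reads) and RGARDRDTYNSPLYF (708 reads), which lacks the conserved cysteine. Pairs differing at 1 nucleotide were 29.5% of the 112 pairs in thymus, 29.9% of the 107 in inguinal node and 73.7% of the 19 in mediastinal node, so separate rearrangements and copies of the larger clonotype altered in amplification cannot be told apart from these counts.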
